A study of Ovis aries with 6 samples.

How the data were processed

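Messenger RNA from cultured sheep mitral valve endothelial cells (VECs) was sequenced after 24 h with plasma from sheep after myocardial infarction (MI) or with naive plasma, in 3 libraries per group. Per the labels' protocols, libraries were made with a stranded mRNA kit and read as paired ends of 150 bp. Groups and replicate numbers were taken from the sample titles, and the columns of the whole-series table were matched to samples by name. No column was left without a sample.

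Per the submitters' processing notes, the authors used STAR 2.5.2b, SAMtools 1.9, featureCounts 2.0.0, FastQC, MultiQC 1.5 and DESeq2 1.26.0 with the sheep build Oar_v3.1. The annotation and the strand setting of the counting are not given in the sources used here. The deposited whole-series table holds raw counts per gene symbol for 18865 rows, of which 17030 had a count in any library. The deposited per-sample files hold a signal that equals these counts divided by 1 factor per library, for 100% of non-zero counts within a tolerance of 0.01%. In each library that factor over the DESeq2 size factor computed here was 1, so the files gave no separate alternative. In total 2461 rows carry provisional locus names and took 17.4% to 18.9% of counts, and 6 ribosomal RNA rows took 0.949% to 1.39%. No row lacked a gene name. Of all symbols, 86.5% were found in a RefSeq gene table of the assembly ARS-UI_Ramb_v3.0, which was used for names alone, and no coordinates are given because the builds differ. Some loci appear under an older and a current symbol, such as CXCL8 and IL-8, so reads of near-identical copies, overlapping genes and antisense partners could be shared and such rows are uncertain.

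Total counts per library were 14858472 to 20672794. A count of 0 was read against a floor of 3 counts per library, equal to 0.145 to 0.202 CPM, the count scaled by the library total. Floors cover counting error alone, since reads without molecular identifiers are not independent molecules.

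Counts were analysed in R 4.3.3. Genes were kept by the edgeR 4.0.16 function filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 14326 genes. Libraries were scaled by TMM, and post-MI plasma was compared with naive plasma by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are post-MI minus naive, with a standard error (SE) equal to the absolute log2 fold change over the square root of the F statistic. CPM values are means with standard deviations (SD) over 3 libraries. Principal components used the 500 most variable genes on log2 CPM with a prior count of 2.

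In advance, 27 gene lists were fixed: endothelial identity, EndMT and mesenchymal genes, TGF-beta target genes, BMP target genes, TGF-beta and BMP ligands and receptors, canonical Wnt target genes, Wnt ligands and receptors, secreted Wnt inhibitors, Notch pathway, inflammatory activation, interferon response, cell cycle, collagens and matrix, hypoxia and glycolysis, cholesterol synthesis and uptake, oxidative stress response, unfolded protein and amino acid stress, glucocorticoid response, oxidative phosphorylation, coagulation and fibrinolysis, YAP and SRF target genes, immediate early genes, and markers of leukocytes, fibroblasts and valve interstitial cells, smooth muscle cells and pericytes, lymphatic endothelium, and red cells and platelets. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM, with an inter-gene correlation preset to 0.01 and adjustment over the 25 lists tested. Camera compares a list's members with the other genes. A list's score in a library is the mean log2 CPM of its members, and scores were compared by a two-sided exact permutation test, whose smallest possible p with 3 libraries against 3 is 0.1.

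Named genes followed a rule fixed at the same time. It took up to 10 genes per direction with the largest change among edgeR calls with an average log2 CPM of at least 1 and non-overlapping CPM, which gave 0 genes. It also took 14 fixed genes (FRZB, PTPRC, ACTA2, SNAI1, SNAI2, TGFB1, PECAM1, CDH5, NOS3, VWF, VIM, CDH2, MMP2 and COL1A1) and up to 4 members with the smallest p in each list. Genes named from the DESeq2 calls or from single libraries, and genes outside the rule that passed over a list alone in a fit without 1 library, were chosen after their values were seen. Some members of the lists are not reported here.

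Alternatives chosen before the data were examined were DESeq2 1.42.0 with its Wald test, limma-voom, DESeq2 size factors within edgeR, no count filter, a filter of 1 CPM in at least 3 libraries, a minimum absolute log2 fold change of 1, the replicate number as a block and each library left out. For lists they were an estimated correlation, limma's fry and camera on voom values. The DESeq2 fits with a block or a library left out, edgeR with robust dispersion and lists on plain library totals were added after seeing the data.

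The tests were tried on 5 simulated data sets of 14326 genes with 200 changed genes. Means, library sizes and the dispersion of each gene as estimated by edgeR were taken from this comparison. edgeR recovered 15.4% of genes changed 2-fold and 81.0% of those changed 4-fold, with 6.64% false calls. DESeq2 recovered 48.0% and 91.4%, with 29.9% false calls, and limma-voom recovered 14.8% and 80.4%, with 6.80% false calls. A simulated 2-fold change of the cell cycle list was called by camera in 5 of 5 data sets, also with an estimated correlation, and 0 of 114 tests of unchanged lists were called. The simulated genes varied independently of each other.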

Results

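The data are gene-level RNA sequencing counts from sheep mitral valve endothelial cells (VECs), the cells that line the leaflets of the mitral valve. The cultures were kept for 24 h with plasma from sheep after myocardial infarction (post-MI plasma, 3 libraries) or with plasma from naive sheep (3 libraries). The labels do not say whether libraries of a group came from separate cultures, plasma donors or cell donors, so p-values measure the spread between these libraries, which may be technical. Total counts were 19916079, 17446474 and 20672794 for naive replicates 1, 2 and 3, and 18747848, 14858472 and 17403288 for post-MI replicates 1, 2 and 3. The series concerns endothelial-to-mesenchymal transition (EndMT), in which endothelial cells take on features of mesenchymal cells, and sFRP3, a secreted Wnt inhibitor encoded by FRZB. Cells given sFRP3 were not analysed here.

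The naive libraries differed more among themselves than the post-MI libraries did along the main axis of variation. On the first principal component, which held 59.2% of the variance of the 500 most variable genes, naive replicate 1 lay at -52.3, and the other libraries lay between -0.50 and 18.5. In naive replicate 1, 65 genes were above and 83 below every other library by more than 2 on the log2 scale. Genes above included SLC2A1 (the main glucose transporter of many cells), PTGS2 (an inducible prostaglandin synthase), IL6 and HMOX1, and genes below included THY1, CLDN5 and MMRN1. These genes were chosen after their values were seen. In post-MI replicate 3, 42 genes lay above every other library by the same margin and 0 below, among them the interferon-induced genes MX2, ISG15 and RSAD2, chosen in the same way.

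**Figure D1:**
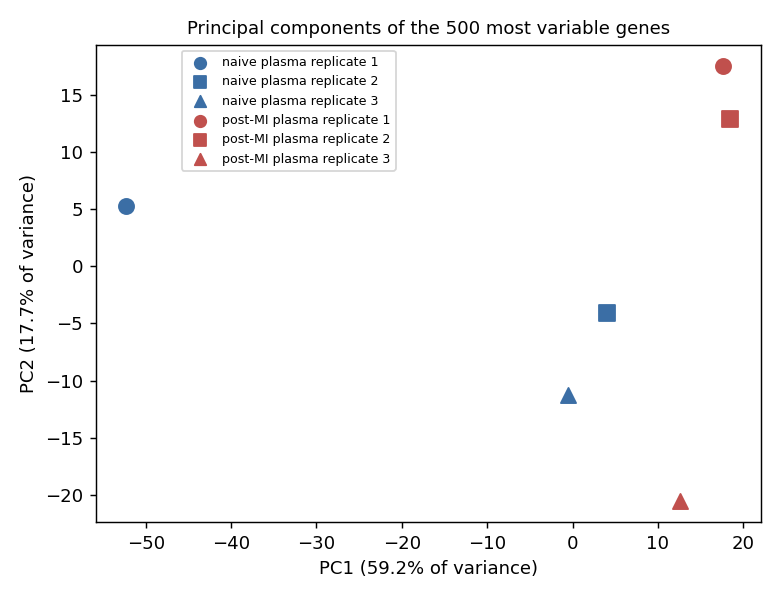
First and second principal components (percent of variance on each axis) of log2 CPM of the 500 most variable genes, with 1 point per library, naive plasma in blue and post-MI plasma in red. Naive replicate 1 lies at -52.3 on the first component, apart from the other 5 libraries.

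The comparison of the groups asked how post-MI plasma changes gene expression in VECs. With post-MI plasma, genes of the oxidative stress response were lower and genes of the cell cycle were higher, as lists in camera with a preset correlation, than with naive plasma. Both lists had an adjusted p = 0.523 with an estimated correlation in camera, and edgeR called 0 single genes. NQO1, a quinone reductase, averaged 371 ± 243 CPM with naive plasma and 45.8 ± 34.4 CPM with post-MI plasma (SD, n = 3 each). PLK1, a mitotic kinase, averaged 11.4 ± 4.41 and 49.9 ± 19.96 CPM (SD, n = 3 each). The EndMT list did not pass its test, and the endothelial junction genes PECAM1 and CDH5 had log2 fold changes of 0.16 and 0.21. With single libraries left out these ran from 0.02 (without naive replicate 2) to 0.31 (without post-MI replicate 3) for PECAM1 and from 0.08 (without naive replicate 3) to 0.39 (without naive replicate 1) for CDH5.

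For single genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower among 14326 tested, with a smallest adjusted p of 0.254. At an unadjusted p under 0.05 it gave 1244 genes, 8.68% of those tested. limma-voom also called 0 genes, with 1185 at an unadjusted p under 0.05, and the DESeq2 Wald test called 152 higher and 66 lower. In simulated data of this design 29.9% of the DESeq2 calls were false, against 6.64% of the edgeR calls. CPM of the groups did not overlap for 1192 genes higher and 1121 lower with post-MI plasma, 16.1% of genes tested, where chance gives 10%. Of the 25 lists tested, camera with a preset correlation called 4 up and 5 down, and 0 of these calls held with an estimated correlation or in fry's directional test. fry's mixed test, which asks whether members change in either direction, called 2 lists.

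The oxidative stress response list fell (median log2 fold change -1.76, camera adjusted p = 1.77e-10; adjusted p = 0.523 with an estimated correlation). It holds genes that defend against oxidants and bind iron. All 11 tested members had a negative log2 fold change, and 9 had CPM that did not overlap between the groups. By edgeR 11 of the 11 passed when adjusted over the list alone, and 0 over all genes tested. SRXN1, which restores peroxiredoxins, was at 162 ± 45.1 CPM with naive and 46.4 ± 18.3 CPM with post-MI plasma (SD, n = 3 each), a log2 fold change of -1.80 ± 0.34 (SE). SLC7A11, the cystine importer, gave -1.85 ± 0.37 and NQO1 gave -3.02 ± 0.73 (SE). Naive replicate 1 had the highest list score of the 6 libraries, 8.13 log2 CPM against 6.87 and 6.98 in the other naive and 5.31 to 6.25 in the post-MI libraries. Without naive replicate 1 the median was -0.99, the camera adjusted p 1.25e-08, and 9 members passed over the list alone.

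The cell cycle list rose (median log2 fold change 0.55, camera adjusted p = 1.77e-10; adjusted p = 0.523 with an estimated correlation). All 20 members had a positive log2 fold change and 13 did not overlap between the groups. By edgeR 10 passed when adjusted over the list alone and 0 over all genes tested. PLK1 gave a log2 fold change of 2.13 ± 0.39, the proliferation marker MKI67 1.81 ± 0.40, and the mitotic cyclins CCNB1 and CCNB2 1.37 ± 0.27 and 1.25 ± 0.24 (SE). MKI67 was at 72.6 ± 36.7 CPM with naive and 254 ± 67.4 CPM with post-MI plasma (SD, n = 3 each). List scores were 4.02 to 4.99 log2 CPM in the naive and 5.50 to 5.60 in the post-MI libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Over the list alone edgeR called 5 members without post-MI replicate 2, and 6 without naive replicate 3 or post-MI replicate 1, with PLK1, MKI67, CCNB1, CCNB2 and BUB1 in each of these fits. Without naive replicate 3, 15 members had a positive and 5 a negative log2 fold change.

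**Figure D2:**
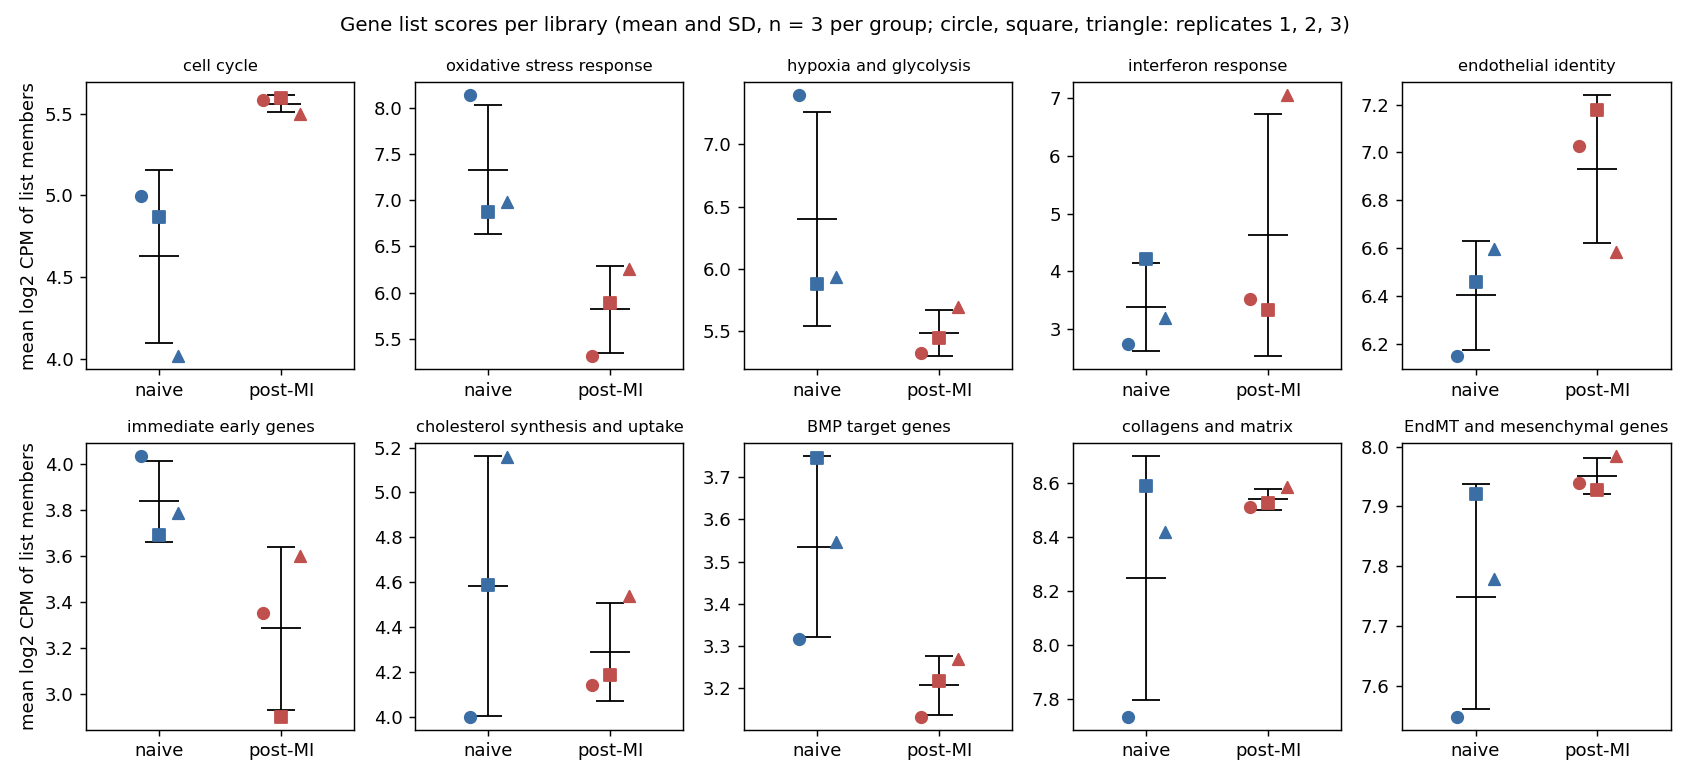
Mean log2 CPM of list members per library for the 9 lists called by camera and for the EndMT list, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3 libraries. Cell cycle scores lie between 4.02 and 4.99 with naive and between 5.50 and 5.60 with post-MI plasma.

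Log2 fold changes of EndMT and mesenchymal genes had both signs and the list did not pass camera (median log2 fold change 0.06, adjusted p = 0.146, and 0.582 with an estimated correlation). Of 23 tested members 13 had a positive and 10 a negative log2 fold change, and 0 passed in edgeR, whether adjusted over the list alone or over all genes. Without naive replicate 2 the camera adjusted p was 0.0416. Over the list alone edgeR called 1 member without naive replicate 1 (SNAI2) and 1 without naive replicate 2 (CNN1, chosen after its values were seen). SNAI2, a transcription factor of mesenchymal transition, was at 23.1 ± 8.06 CPM with naive and 45.7 ± 4.86 CPM with post-MI plasma (SD, n = 3 each), a log2 fold change of 0.99 ± 0.27 (SE, edgeR adjusted p = 0.489). Its relative SNAI1 gave -0.81 ± 0.52 (SE, edgeR adjusted p = 0.639), and -0.10 without naive replicate 1. Smooth muscle actin ACTA2 was at 2335 ± 1824 and 4674 ± 777 CPM (SD, n = 3 each; edgeR adjusted p = 0.619), and naive replicate 1 alone was at 643 CPM. TAGLN gave a log2 fold change of 0.76 ± 0.34 and POSTN -1.44 ± 0.54 (SE), with POSTN at 3061 CPM in naive replicate 1 and 503 to 868 CPM in the other 5 libraries. VIM gave 0.23 ± 0.30, CDH2 -0.09 ± 0.31, MMP2 -0.45 ± 0.32, COL1A1 0.19 ± 0.39 and TGFB1 0.15 ± 0.13 (SE). The sign of CDH2 turned without naive replicate 2 (0.31) or without post-MI replicate 2 (0.08), and that of COL1A1 without naive replicate 1 (-0.14). Without naive replicate 1 VIM gave 0.06, MMP2 -0.15, TAGLN 0.48, ACTA2 0.57 and POSTN -0.48. Without naive replicate 2 MMP2 gave -0.74, TAGLN 1.17, ACTA2 1.77 and COL1A1 0.58, and VIM gave 0.46 without naive replicate 3.

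Endothelial identity genes rose as a list (median log2 fold change 0.38, camera adjusted p = 0.00454, and 0.523 with an estimated correlation). List scores overlapped, at 6.15 to 6.60 log2 CPM in the naive and 6.59 to 7.18 in the post-MI libraries (exact two-sided permutation p = 0.2). Post-MI replicate 3, at 6.59, lay just below naive replicate 3. Of 20 members 15 had a positive log2 fold change and 4 did not overlap, and 0 passed in edgeR over the list alone or over all genes (4 over the list alone without post-MI replicate 3: EGFL7, ROBO4, SOX18 and VWF, of which SOX18 was chosen after its values were seen). The tight junction gene CLDN5 was at 2.72 ± 2.22 CPM with naive and 13.2 ± 7.59 CPM with post-MI plasma, and the guidance receptor ROBO4 at 16.4 ± 4.51 and 40.5 ± 17.5 CPM (SD, n = 3 each). VWF, stored in endothelial granules, gave a log2 fold change of 1.43 ± 0.49 (SE, edgeR adjusted p = 0.555). PECAM1 gave 0.16 ± 0.22, CDH5 0.21 ± 0.20 and the nitric oxide synthase NOS3 -0.13 ± 0.26 (SE). PECAM1 gave 0.02 without naive replicate 2 and 0.31 without post-MI replicate 3, and CDH5 0.39 without naive replicate 1 and 0.08 without naive replicate 3. The sign of NOS3 turned without naive replicate 1 (0.03) or without post-MI replicate 1 (0.09).

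Genes of hypoxia and glycolysis fell as a list (median log2 fold change -1.16, camera adjusted p = 3.44e-05; adjusted p = 0.523 with an estimated correlation). Of 15 tested members 14 had a negative log2 fold change, 5 did not overlap and 0 passed in edgeR over the list alone or over all genes. Naive replicate 1 had a score of 7.39 log2 CPM, against 5.87 and 5.93 in the other naive and 5.32 to 5.69 in the post-MI libraries. Lactate dehydrogenase LDHA was at 1884 CPM in naive replicate 1 and 243 to 826 CPM elsewhere, and SLC2A1 at 118 CPM and 13.3 to 20.1 CPM elsewhere. Without naive replicate 1 the median was -0.43 and the camera adjusted p 0.000195, and over the list alone edgeR called 9 members without naive replicate 2 and 7 without naive replicate 3. NDRG1 gave a log2 fold change of -1.50 ± 0.42 and the glycolytic enzyme ENO1 -1.17 ± 0.46 (SE), and without naive replicate 1 these were -0.89 and -0.43.

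Immediate early genes, induced within minutes to hours of a stimulus, fell as a list (median log2 fold change -0.61, camera adjusted p = 0.00499; adjusted p = 0.523 with an estimated correlation). Of 14 tested members 11 had a negative log2 fold change, and 0 passed in edgeR over the list alone or over all genes. KLF2, a flow-responsive endothelial transcription factor, was at 22.2 ± 9.81 CPM with naive and 7.10 ± 1.97 CPM with post-MI plasma, and KLF4 at 25.6 ± 12.4 and 9.96 ± 4.65 CPM (SD, n = 3 each). Without post-MI replicate 2 the camera adjusted p was 0.0591. Over the list alone edgeR called KLF2 without naive replicate 2 and FOSL1, chosen after its values were seen, without post-MI replicate 3.

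BMP target genes fell as a list (median log2 fold change -0.37, camera adjusted p = 0.0427; adjusted p = 0.523 with an estimated correlation), with an adjusted p of 0.00527 in fry's mixed test. Of 9 tested members 7 had a negative log2 fold change, and 1 passed in edgeR when adjusted over the list alone and 0 over all genes. That member was ID2, an inhibitor of helix-loop-helix factors, at 25.5 ± 2.75 CPM with naive and 14.2 ± 1.38 CPM with post-MI plasma (SD, n = 3 each). ID1 gave a log2 fold change of -1.75 ± 0.61 (SE). The camera adjusted p was 0.123 without naive replicate 2, 0.110 without post-MI replicate 1 and 0.0943 without post-MI replicate 3, and ID2 passed over the list alone in each of these fits. With ID2, edgeR called ID1 over the list alone without naive replicate 2 or post-MI replicate 3, and BMPER, chosen after its values were seen, without naive replicate 1.

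Cholesterol synthesis and uptake genes fell as a list (median log2 fold change -0.24, camera adjusted p = 0.0297; adjusted p = 0.757 with an estimated correlation). Of 17 members 16 had a negative log2 fold change, and 0 passed in edgeR over the list alone or over all genes. HMGCS1 of the mevalonate pathway gave -0.85 ± 0.25 and the squalene epoxidase SQLE -0.63 ± 0.22 (SE; SQLE -0.39 without naive replicate 3). The camera adjusted p was 0.0613 without naive replicate 2, 0.965 without naive replicate 3, 0.0901 without post-MI replicate 1 and 0.0591 without post-MI replicate 2. The median was 0.02 without naive replicate 3. Without naive replicate 1 the median was -0.54, the camera adjusted p 1.12e-07 and all 17 log2 fold changes negative, and edgeR called 4 members over the list alone (CYP51A1, HMGCS1, MSMO1 and SQLE, of which MSMO1 was chosen after its values were seen).

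Collagens and matrix genes rose as a list (median log2 fold change 0.31, camera adjusted p = 0.0427; adjusted p = 0.582 with an estimated correlation). Of 25 members 17 had a positive log2 fold change, and 0 passed in edgeR over the list alone or over all genes. Basement membrane collagen COL4A2 gave 0.79 ± 0.28, while the members LOXL2, TIMP1 and VCAN gave -0.58 ± 0.19, -0.81 ± 0.29 and -0.96 ± 0.37 (SE; VCAN -0.42 without naive replicate 1). The camera adjusted p was 0.519 without naive replicate 1, 0.0520 without post-MI replicate 1 and 0.149 without post-MI replicate 3.

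Interferon response genes rose as a list (median log2 fold change 2.66, camera adjusted p = 0.00209; adjusted p = 0.646 with an estimated correlation). The score was 7.05 log2 CPM in post-MI replicate 3 and 2.74 to 4.22 in the other 5 libraries. MX2, an interferon-induced antiviral GTPase, was at 328 CPM in post-MI replicate 3 and 0.705 to 8.69 CPM elsewhere. All 17 members had a positive log2 fold change, 1 did not overlap, and 0 passed in edgeR over the list alone or over all genes. IFI44 gave a log2 fold change of 3.56 ± 1.54, IFIT3 2.69 ± 1.03 and IRF7 2.65 ± 1.14 (SE). Without post-MI replicate 3 the median was -0.23 and the camera adjusted p 0.808, and the log2 fold changes of MX2, IFI44, IFIT3 and IRF7 were -0.71, -0.16, 0.40 and 0.07.

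FRZB was near the floor of detection. It had 0, 3 and 5 counts in naive replicates 1, 2 and 3 and 27, 20 and 1 counts in post-MI replicates 1, 2 and 3, or 0.136 ± 0.122 and 0.957 ± 0.780 CPM (SD, n = 3 each). A count of 0 in naive replicate 1 allows up to 0.151 CPM. FRZB was below the count filter, and without the filter edgeR gave a log2 fold change of 2.75 ± 1.15 (SE, adjusted p = 0.615). Secreted Wnt inhibitors did not pass camera as a list (5 tested members, median log2 fold change 0.06, adjusted p = 0.434). With 6 members tested, the median was -0.09 without naive replicate 1, 0.38 without naive replicate 2 and 0.73 without naive replicate 3. SFRP1, another secreted Wnt inhibitor, was at 28.0 ± 19.0 CPM with naive and 85.5 ± 40.8 CPM with post-MI plasma (SD, n = 3 each; edgeR adjusted p = 0.558). Over the list alone edgeR called FRZB and SFRP1 without post-MI replicate 3, where 6 members were tested, and SFRP1 without naive replicate 2. Canonical Wnt target genes gave a camera adjusted p of 0.539 over 7 tested members (median 0.06), and Wnt ligands and receptors 0.0897 over 16 (median 0.30). Without naive replicate 2 the camera adjusted p of the Wnt ligands and receptors was 0.00823. In that list edgeR called 0 members over the list alone with all 6 libraries, WNT5A without naive replicate 1, and FZD7 and FZD8 without naive replicate 2.

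TGF-beta target genes gave a median log2 fold change of -0.14 (camera adjusted p = 0.831) and TGF-beta and BMP ligands and receptors 0.18 (camera adjusted p = 0.0705). The ligand TGFB2 was at 29.4 ± 13.3 CPM with naive and 54.4 ± 2.60 CPM with post-MI plasma, and the receptor TGFBR2 at 113 ± 52.0 and 200.1 ± 17.5 CPM (SD, n = 3 each). Their log2 fold changes were 0.89 and 0.83, and 0.58 and 0.49 without naive replicate 1. Notch pathway genes gave a median of 0.50 (camera adjusted p = 0.0567), with NOTCH1 at a log2 fold change of 0.60 ± 0.18 and NOTCH2 at -0.67 ± 0.20 (SE). Glucocorticoid response genes gave a median of 0.32 (camera adjusted p = 0.0567), and 1 member, ERRFI1, a feedback inhibitor of growth factor receptors, passed in edgeR when adjusted over the list alone, at 0.90 ± 0.17 (SE). Coagulation and fibrinolysis genes gave a median of 0.03 (camera adjusted p = 0.577), and 1 member, the clotting factor F8, passed over the list alone, at 1.53 ± 0.36 (SE). Inflammatory activation genes gave a median of 0.13 (camera adjusted p = 0.541), with IRF1 at 1.06 ± 0.29 and PTGS2 at -3.26 ± 1.08 (SE). PTGS2 was at 255 CPM in naive replicate 1 and 7.10 to 20.7 CPM elsewhere, and its log2 fold change without naive replicate 1 was -0.87. Median and camera adjusted p were -0.35 and 0.162 for unfolded protein and amino acid stress, -0.04 and 0.217 for oxidative phosphorylation, and 0.16 and 0.0932 for YAP and SRF target genes. In these lists edgeR called 0 genes over all genes tested, and over the list alone, with all 6 libraries, it called 0 besides ERRFI1 and F8. F8 passed over the list alone without naive replicate 3 or post-MI replicate 3 and in no other fit without 1 library, and ERRFI1 did not pass without naive replicate 2 or post-MI replicate 1. Leaving out 1 library gave further calls over the list alone, among which HEY2, JAG1, PHGDH, FKBP5 and ZBTB16 were chosen after their values were seen. In the Notch pathway these were HEY2, JAG1 and NOTCH1 without naive replicate 2, and DLL4 and NOTCH2 without post-MI replicate 3. In unfolded protein and amino acid stress they were ASNS, CHAC1, PHGDH and PSAT1 without naive replicate 3, in inflammatory activation IRF1 and TNFAIP3 without post-MI replicate 2, and in coagulation PLAT and VWF without post-MI replicate 3. In glucocorticoid response they were FKBP5 without naive replicate 1, PDK4, PER1 and ZBTB16 without naive replicate 3, and DUSP1 without post-MI replicate 3. Leaving out 1 library also gave camera calls in several of these lists. Without naive replicate 2 the adjusted p was 0.0203 for TGF-beta and BMP ligands and receptors, 0.0203 for the Notch pathway and 0.00174 for YAP and SRF targets. Without post-MI replicate 3 it was 0.0385 for the Notch pathway, and without post-MI replicate 2 it was 0.0455 for YAP and SRF targets and 0.0404 for inflammatory activation. Glucocorticoid response gave 0.0238 without naive replicate 1 and 0.0182 without naive replicate 3, and unfolded protein and amino acid stress gave 7.6e-06 without naive replicate 3 and 0.0414 without post-MI replicate 1.

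Markers of other cell types gave no call by camera. Leukocyte markers had 5 tested members (camera adjusted p = 0.196, direction up, mean log2 fold change 0.48, median -0.20) and an adjusted p of 0.0240 in fry's mixed test. PTPRC, which encodes the leukocyte surface protein CD45, had 4, 6 and 3 counts in naive and 12, 12 and 23 counts in post-MI replicates 1, 2 and 3, a log2 fold change of 2.01 ± 0.54 (SE, edgeR adjusted p = 0.443). PTPRC passed in edgeR when adjusted over the list alone, and 0 members passed over all genes. Of the 6 fits without 1 library, PTPRC passed over the list alone in 2 (without naive replicate 2 or post-MI replicate 1). Fibroblast and valve interstitial markers (camera adjusted p = 0.739) had a median of -0.42 and a mean of -0.09, while camera gave the direction up. Smooth muscle and pericyte markers gave a median of 0.47 (camera adjusted p = 0.146, and 0.0220 without naive replicate 2). This median was 0.07 without naive replicate 1, 1.10 without naive replicate 2 and 0.22 without post-MI replicate 3. Without naive replicate 2 edgeR called CSPG4, KCNJ8, LMOD1 and MYH11 over the smooth muscle list alone and SFRP1 over the fibroblast list alone, where it called 0 with all 6 libraries. Lymphatic endothelial markers (3 tested members, median 0.57, mean -0.18) and red cell and platelet markers (2 tested members, median -0.18) were too few to test.

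**Figure D3:**
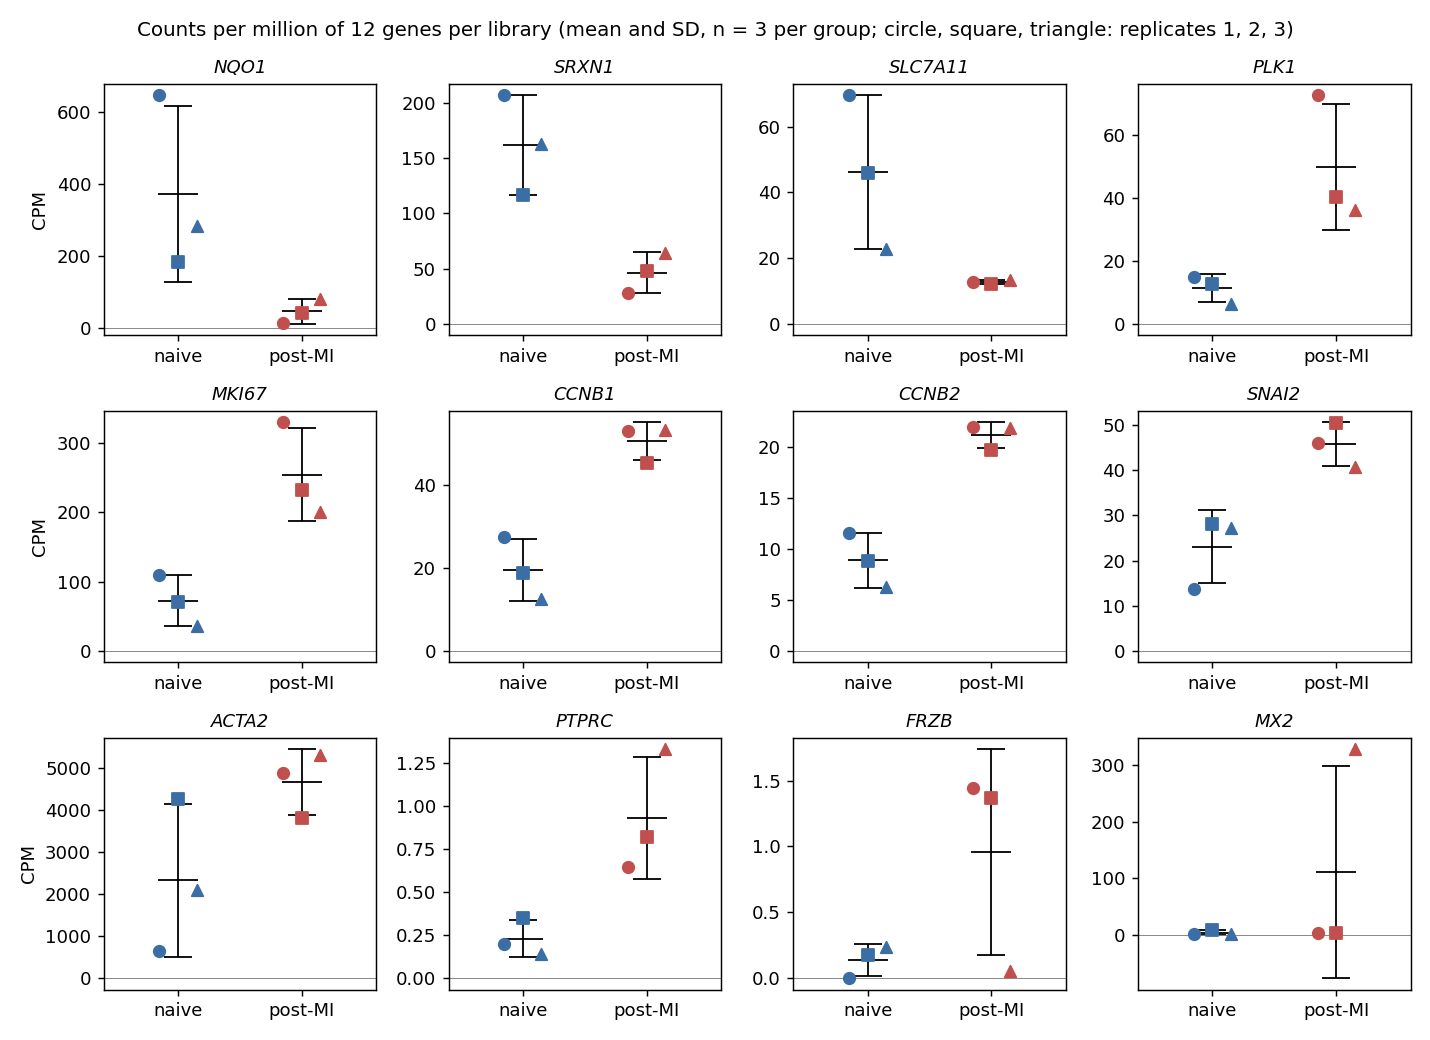
CPM of 12 genes in each library, with circles, squares and triangles for replicates 1, 2 and 3 of naive plasma (blue) and post-MI plasma (red) and bars for the mean and SD of 3 libraries. NQO1 averages 371 CPM with naive and 45.8 CPM with post-MI plasma, and MX2 reaches 328 CPM in post-MI replicate 3 alone.

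The genes called by DESeq2 were named after their values were seen. Of its 218 calls, 152 higher and 62 lower genes had an average log2 CPM of at least 1 and CPM that did not overlap between the groups. Higher genes included the mitotic genes CDCA3 (log2 fold change 2.33 ± 0.32) and PIMREG (2.35 ± 0.41), the retinaldehyde reductase DHRS3 (2.23 ± 0.32) and the endothelial lectin CLEC1A (2.41 ± 0.60), with edgeR SE. Lower genes included the amino acid transporter SLC38A3 (-2.93 ± 0.44) and the AMP deaminase AMPD3 (-2.83 ± 0.82), with edgeR SE. DESeq2 adjusted p was 6.02e-08 for CDCA3, 1.13e-07 for DHRS3 and 1.38e-05 for SLC38A3, against edgeR adjusted p of 0.254 for each. With single libraries left out the DESeq2 calls ranged from 52 (without post-MI replicate 1) to 235 (without naive replicate 2) higher genes and from 9 (without post-MI replicate 2) to 153 (without naive replicate 2) lower genes. They were 73 higher without post-MI replicate 2, 19 lower without post-MI replicate 1, and 109 and 110 lower without naive replicate 3 and post-MI replicate 3. Of the 152 higher genes 51 (without post-MI replicate 1) to 134 (without naive replicate 1) were called again, with 68 without post-MI replicate 2. Of the 66 lower genes 9 (without post-MI replicate 2) to 54 (without naive replicate 2) were called again, with 14 without post-MI replicate 1, 31 without naive replicate 1 and 37 without naive replicate 3.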

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

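The DESeq2 fits with a block or a library left out, edgeR with robust dispersion, and lists on plain library totals were chosen after seeing the data. The counts of 0 genes higher and 0 lower in edgeR stayed at 0 with DESeq2 size factors, no filter, the stricter filter, robust dispersion, a minimum fold change, limma-voom and each library left out, while the DESeq2 Wald test gave 152 higher and 66 lower; the cause was not tested. Without single libraries DESeq2 gave 52 to 235 higher and 9 to 153 lower genes, with fewer samples in each fit. The 9 list calls became 0 with an estimated correlation and 0 with fry's directional test, and both allow for correlation between members. With an estimated correlation camera also takes its degrees of freedom from the few libraries, and not from the number of genes tested. The loss of calls can therefore not be credited to correlation alone. Estimated correlations of the 9 lists ran from 0.0035 (BMP targets) to 0.934 (interferon). The BMP estimate lay below the preset 0.01, so correlation between its own members does not account for the loss of that call. The calls were 7 to 13 without single libraries (6 to 8 of the 9 and 1 to 6 others). They were 12 without the filter (9 and 3), 10 on voom values (9 and 1) and 11 on plain totals (9 and 2). The first principal component held 49.5% of the variance over all tested genes and 59.6% with a prior count of 0.5, against 59.2%.

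Replicate numbers showed no clear pairing of the samples. Deviations of same-numbered libraries correlated at 0.151, -0.109 and 0.0924, and among the naive libraries replicate 1 alone correlated best with its own number. With 3 libraries per group this cannot exclude a pairing, which the labels do not state. With the replicate block edgeR called 0 genes higher and 0 lower, DESeq2 called 151 and 58, and camera called 12 lists (the 9 and 3 others). The fibroblast list turned to down with the block (adjusted p = 0.964).

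Among lists called with all 6 libraries the camera direction did not turn, but the median did for interferon (-0.23 without post-MI replicate 3) and cholesterol (0.02 without naive replicate 3). Without the filter, canonical Wnt targets and leukocyte markers turned to down (camera adjusted p = 0.990 and 0.932); the cause was not tested. Other turns came without 1 library, with fewer samples. Over those 6 fits the camera adjusted p ran from 0.214 to 0.960 for TGF-beta targets (up without naive replicate 1), 0.216 to 0.808 for canonical Wnt targets (down without naive replicate 1 or post-MI replicate 3), 0.0905 to 0.757 for secreted Wnt inhibitors (down without naive replicate 1), 0.0404 to 0.965 for inflammatory activation (down without naive replicate 2 or post-MI replicate 3), 0.103 to 0.960 for oxidative phosphorylation (up without post-MI replicate 1), 0.00174 to 0.785 for YAP and SRF targets (down without naive replicate 1) and 0.119 to 0.808 for fibroblast markers (down without naive replicate 1 or post-MI replicate 3). Log2 fold changes ran from -0.29 to 0.085 for NOS3, -0.28 to 0.31 for CDH2, -0.14 to 0.58 for COL1A1, -0.71 to 6.50 for MX2, -0.16 to 4.61 for IFI44 and -0.73 to 0.063 for MSMO1. Of the other settings of single lists, 283 kept direction and side of the threshold, 30 lost and 22 gained a call. Among those of single genes 1110 kept both and 20 gained a call. The edgeR and limma-voom settings called 0 genes, so no single gene could lose a call and the gains came from the DESeq2 Wald test. For single genes the tally thus tells about direction, and not about the size of a change.

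The depth limits genes near the floor, such as FRZB and PTPRC.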

Other observations

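The tests of the oxidative stress result against naive replicate 1 and against other cell types, the tests on post-MI replicate 3, the depth test on naive replicate 1, and the tests on mitotic genes and FRZB were chosen after the result was seen. The cell cycle list was divided into 10 mitotic and 10 DNA replication members after their values were seen, so the 2 parts do not test whether they differ. Their median log2 fold changes were 1.34 and 0.43. Means of the replication members overlapped between the groups, at 4.50 to 5.40 log2 CPM in the naive and 5.30 to 5.64 in the post-MI libraries. Adjusted over each part alone, edgeR called 9 mitotic and 0 replication members. The mean of the mitotic minus that of the replication members was -1.06 to -0.75 in the naive and -0.22 to 0.58 in the post-MI libraries, a gap of 0.530 between the groups (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows), which decides nothing.

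Among markers of leukocytes PTPRC was counted in each library, yet 8 abundant leukocyte transcripts (CD52, TYROBP, CD3E, MS4A1, AIF1, ITGAM, CSF1R and CD4) together reached 0.231 to 1.36 CPM, highest in naive replicate 3. FRZB counts of 27, 20 and 1 in the post-MI libraries gave an exact multinomial p of 2.41e-07 against counting noise alone, which sets single libraries against technical noise and decides nothing about the spread.

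Chance was examined with the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05. edgeR called 0 genes in the real split and at most 0 in the others, so 10 of 10 gave as many. Any split reaches a count of 0, so this tells nothing about chance. DESeq2 called 218 genes in the real split and at most 107 in the others, so 1 of 10 gave as many. Camera called 9 lists in the real split and at most 12 in the others, so 4 of 10 gave as many.

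Lower oxidative stress genes with post-MI plasma were weighed first. The difference did not rest on naive replicate 1 alone, since the median log2 fold change without it was -0.988. Each other naive library also scored above each post-MI library. That adds no support, because the scores did not overlap with all 6 libraries, and leaving 1 out cannot make them overlap. Scaling did not account for it, as the list's median moved by 0.0231 between 3 scalings while the median of all genes stayed between -0.04 and -0.01. A loss of contaminating cells would lower their markers alike, but with all 6 libraries the lowest of the fibroblast, smooth muscle and leukocyte medians was -0.418. Naive replicate 1 was itself low in fibroblast and smooth muscle markers (-1.28 and -1.03 relative to the other naive libraries). Without it the fibroblast median was -0.495, and the smooth muscle and leukocyte medians were 0.07 and 0.19. A loss of fibroblasts is thus not excluded as a part of the difference. A response of the cells to post-MI plasma, or a difference in the naive plasma, stays open as a hypothesis, and plasma content was not tested.

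Interferon genes in post-MI replicate 3 were weighed second. Leukocytes carried into this library would bring their abundant transcripts, whose sum was 0.231 CPM there, the lowest of the 6 libraries. Each of these transcripts was below the floor of 0.172 CPM in this library, and CD52 and MS4A1 were at 0 CPM in every library. PTPRC, which is not in the sum, was highest in this library, at 1.33 CPM against 0.141 to 0.820 CPM elsewhere. A few leukocytes are thus not excluded. The library's total of 17403288 counts lay within the range of the others. An exchange with a naive library would move this library's interferon score of 7.05 to the other group and would not produce it. The other libraries scored 2.74 to 4.22. Whether the labels were exchanged stays open. The oxidative stress score of this library lay 0.618 below the lowest naive library. Its cell cycle score was 5.50, against 4.02 to 4.99 in the naive libraries. Both values run against an exchange, but these lists were singled out because they part the groups. Over all tested genes this library correlated best with naive replicate 2 (r = 0.976, against 0.972 and 0.963 with the other post-MI libraries). No biological explanation was tested.

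The distance of naive replicate 1 from the other naive libraries was weighed last. More fibroblasts or smooth muscle cells would raise their markers, but both list medians were lower, at -1.28 and -1.03 relative to the other naive libraries. Whether this library held fewer such cells was not tested. Its total of 19916079 counts lay within the range of the others, and its 10 most abundant genes took 0.934 times the share they took in the other naive libraries. Culture density and oxygen, which could differ between wells, are not in the labels and stay open, as does the plasma used.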
